A study of Drosophila melanogaster with 3 samples.

How the data were processed

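Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole *Drosophila melanogaster* embryos of mixed sex, collected 0 to 24 h after egg laying. Per the labels, the flies were a transgenic line expressing zf30C, a zinc finger protein, with GFP at its C-terminal end. There were 3 libraries, labelled as biological replicates 1 to 3 of a single group. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. The labels give zf30C as the antibody target and name a separate control experiment, while their free-text description calls the same libraries an input control. Here the libraries were treated as immunoprecipitated samples, since the accompanying notes pair each of them with another alignment used as control. That contradiction between the labels remains, and no control library was analysed here.

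Per the file headers and accompanying notes, 5 region lists were made on genome build dm6. Each replicate list came from the alignments of that replicate and of 1 control, which was shared by the 3 replicates. A pooled list came from the alignments of all 3 replicates and that control. A final list holds the regions that passed a threshold on the irreproducible discovery rate (IDR), a measure of how consistently regions rank between replicates. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each list gives a region, a summit position, a signal value and a −log10 q-value. The signal values were used as the authors deposited them, and the sources used here do not say in what unit or relative to what depth they are. The −log10 q-values are also those the authors deposited; they were the same for every summit of the IDR list, 3.96, and were not used to rank. No read counts were in the lists, so the depth behind each region is unknown and no interval on a region's height is given.

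The pooled list and the 3 replicate lists held 30000 summits each, and the IDR list held 3567. Every IDR-list summit was found in the pooled list with the same position and signal, and together they were exactly its 3567 highest summits by signal. The regions against which the IDR list was compared were therefore lower-ranked regions of the same pooled list. Of these, 25574 overlapped no IDR-list region; another 859 pooled summits lay in regions overlapping one and were left out of the background. Some regions held several summits, and the IDR list covered 3426 distinct regions. A summit of the IDR list is called a peak here.

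Positions were compared with the Ensembl release 115 annotation (BDGP6.54) and with the sequence of *D. melanogaster* Release 6, the assembly that dm6 denotes. No coordinate in any list lay beyond the end of its arm. The 6 main arms 2L, 2R, 3L, 3R, 4 and X were used. Transcription starts were the starts of all annotated transcripts except those of transposable elements, 23581 positions in all. Coordinates are given counting from 1.

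A replicate was taken to support a peak when 1 of its own 3567 highest regions by signal overlapped the peak by at least 1 bp. The chance value came from 1000 random draws of as many regions from each replicate list. The IDR and pooled lists were made from the same replicates, so this support is a description of how the lists relate and not an independent test. Rank agreement was the Spearman correlation, across peaks, of the highest overlapping signal in each pair of replicates. Peaks are not independent replicates, and no p-value is attached to it. For single peaks the percentile of this signal among all peaks is given as mean ± SD over the 3 replicates; a peak in no region of a replicate's list was placed lowest there. Peaks that share a region share these values.

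Each summit was placed in the first class that applied of promoter (within 500 bp of a start), 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. The non-coding exon class was added after the data were examined, because such summits had no class in the original scheme. Shares were compared with two-sided Fisher's exact tests and adjusted by the Benjamini-Hochberg method over classes, arms, gene lists or motifs. A gene was called bound when a peak lay within 500 bp of any of its starts, and genes were compared only with other genes that had a pooled-list region there. All intervals are exact (Clopper-Pearson) 95% intervals and cover counting error only. Symbols in the lists were matched through gene names and synonyms. The lists held 6 more symbols than distinct genes matched, where a symbol either found no gene or named a gene already in its list.

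Motifs were searched on both strands of 201 bp windows centred on summits. The background was an equal number of other pooled-list windows matched on class and on GC content in bins of 5 percentage points. The BEAF-32 pair was counted only where both CGATA matches did not overlap. For 6-mers, each peak was its own control. Presence within 50 bp of the summit was compared with presence in the same peak's flanks by an exact McNemar test, with both strands merged. The flanks ran from 200 to 252 bp on either side; the planned flanks were a few bases shorter and held fewer 6-mer starts than the summit window, so they were lengthened to match it.

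The 23 gene lists, the 11 motifs, the tests, most alternatives and the rule for named peaks and genes were fixed before the data were examined. By that rule the text names the 15 peaks of highest signal among the top regions of all 3 replicates, every peak in or within 1000 bp of zf30C, and the 3 peaks with the lowest worst rank in a replicate. It also names, for each gene list, up to 4 bound genes with the highest promoter peak. Peaks missing from a replicate's list tied for lowest and were taken in order of pooled signal. Any other gene named below was chosen after its values were seen.

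The tests were checked on simulated data. Words planted in 5% and in 10% of shuffled summit windows were recovered in 10 of 10 cases each among the 2080 6-mers tested, and 4 unrelated words were also called. Bases of each peak's summit and flank windows were pooled before shuffling, so both had the same composition. The real windows differed, at 37.9% and 43.1% GC, and words called through that difference were not simulated. For gene lists drawn from 6151 genes, lists of the sizes of the ribosomal protein lists were called in 79% of 100 cases at 2 times the usual bound rate and in 100 of 100 at 3 times. Unchanged lists were called in 0.2% and 0.3% of cases. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

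Alternatives covered the 1783 peaks of highest signal in the IDR list, each replicate left out in turn, peaks supported by all 3 replicates, other overlap rules and list lengths, and a Pearson correlation. They also covered promoter windows of 200 and 1000 bp, other backgrounds, a 101 bp motif window, flanks 400 bp away, 1 summit per region, and each summit given to its nearest gene only. Another background, the 3567 other pooled regions next in rank (ranks 3568 to 7385), was used for classes, arms, genes and motifs; for motifs 529 summits found no match there and were left out. The last 3 of these, with 1 summit per region, with nearest genes only and with the regions next in rank, were added after the data were examined. There was only 1 group, so no conditions were compared.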

Results

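The genomic positions occupied by the GFP-tagged zinc finger protein zf30C in 0 to 24 h *Drosophila* embryos were described from 3 biological replicates of 1 group. No second condition was analysed here, so the questions addressed were where the sites lay, which genes they adjoined, what sequence they held and how far the replicates supported them. The data were lists of regions with a signal value each. The sequencing depth of the replicates is unknown, because the lists hold no read counts.

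The authors' IDR list held 3567 peaks in 3426 distinct regions, with a median width of 440 bp. Pooled signal ran from 193.0 to 12466 with a median of 332. Signal in the replicate lists reached 6431 in replicate 1, 3309 in replicate 2 and 2808 in replicate 3, on scales that cannot be compared between lists. Of the 3567 peaks, 88.5% lay among the 3567 highest regions of replicate 1, 82.5% among those of replicate 2 and 81.4% among those of replicate 3. All 3 replicates supported 2328 peaks, or 65.3% (exact 95% interval 63.7 to 66.8%), against 0.46% in random draws of as many regions, of which the highest gave 0.90%. A further 803 peaks had the support of 2 replicates, 414 of 1 replicate and 22 of none. Across peaks, signal correlated with a Spearman coefficient of 0.83 between replicates 1 and 2, 0.74 between 1 and 3, and 0.81 between 2 and 3.

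Support fell along the list. Every peak ranked 1 to 357 by pooled signal was among the top regions of all 3 replicates, as were 87.7% of those ranked 1429 to 1785 and 5.62% of those ranked 3212 to 3567. The share supported by all 3 replicates therefore depended on where the list ended: it was 96.9% for the 1783 highest peaks, and 39.3% or 91.3% when 0.5 or 2 times as many regions of each replicate were considered.

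**Figure D1:**
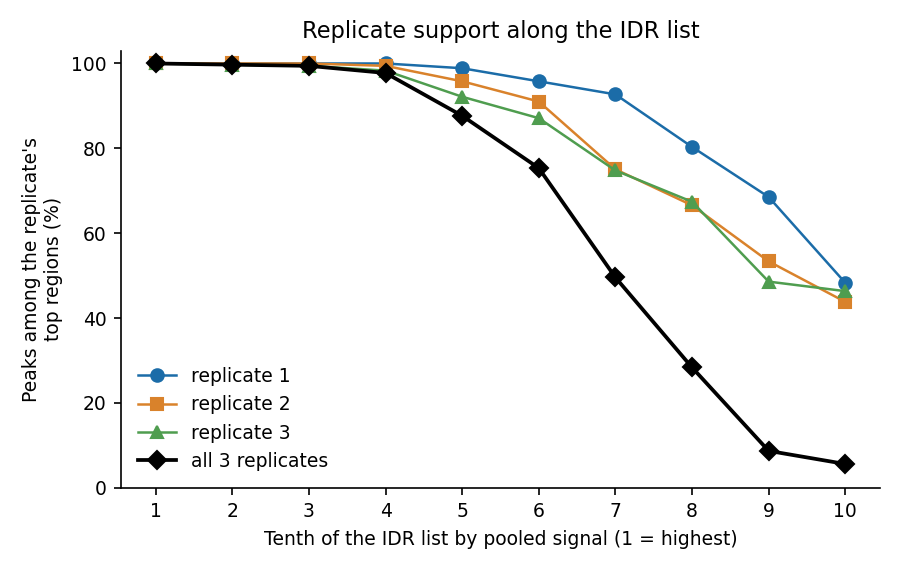
Percent of IDR-list peaks that overlap the 3567 highest regions of each replicate (coloured lines) or of all 3 replicates (black line), for 10 equal groups of peaks ordered by pooled signal, with group 1 the highest. The black line starts at 100%, lies at 97.8% in group 4 and ends at 5.62%.

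The strongest peak lay at px (plexus, a gene of wing vein patterning; FBgn0003175). Its region on arm 2R, 22513868 to 22514739 in dm6, had its summit 202 bp upstream of an annotated px start, a pooled signal of 12466, and rank 1 in all 3 replicates. The peak with rank 2 in each replicate lay in an intron of Lk6, which encodes a protein kinase (FBgn0017581), at 3R, 11760617 to 11761568, with a signal of 9600. Rank 3 in each replicate was the promoter of zf30C itself. Rank 4 in each replicate lay 189 bp upstream of a start of aay, which encodes a phosphoserine phosphatase (FBgn0023129), at 3L, 9422580 to 9423489, with a signal of 7013.

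The next peaks lay at cbt, numb, gish and aop. A peak with a signal of 5926 lay 395 bp upstream of cbt (cabut, a zinc finger transcription factor; FBgn0043364), at 2L, 479569 to 480478, within the gene ush. Peaks stood 144 bp upstream of a start of numb, an inhibitor of Notch signalling (2L, 9449140 to 9450020, signal 5742), and 160 bp upstream of one of gish, a casein kinase (3R, 16280103 to 16281118, signal 5457). An intronic peak of aop, which encodes an ETS-domain repressor, lay 3426 bp upstream of its nearest start (2L, 2164474 to 2165475, signal 5401). The mean percentile of these last 4 peaks was 99.8 ± 0.016, 99.6 ± 0.30, 99.7 ± 0.11 and 99.7 ± 0.29 in that order (SD, n = 3).

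The remaining 7 of the 15 strongest peaks supported by all replicates had signals from 4721 to 4995 and mean percentiles from 99.5 to 99.7. One on the X arm lay 197 bp upstream of the non-coding RNA gene lncRNA:CR45668 and 675 bp upstream of a start of Act5C, a cytoplasmic actin gene. Promoter peaks stood 94 bp upstream of a start of Fkbp14 on 2R, 119 bp upstream of one of CG13921 on 3L, and 215 bp upstream of starts of CG8788 and CG44286 on 2R. Intronic peaks lay in CG11050 on 2L, in mbc (myoblast city, required for myoblast fusion) on 3R, and in cno (canoe, a junction protein) on 3R.

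The peaks with the lowest worst rank in a replicate were missing from that replicate's list altogether. This happened to 10 peaks in replicate 1, 13 in replicate 2 and 10 in replicate 3. The strongest of these lay in an intron of shn, which encodes a zinc finger transcription factor (2R, 11194536 to 11194902, signal 846), and had ranks 491 and 546 in replicates 1 and 2 but no region in replicate 3. Another lay in an exon of lncRNA:CR46204, 650 bp upstream of a start of dl (dorsal; 2L, 17450898 to 17451142, signal 493), and one more 1294 bp upstream of by (3R, 9534196 to 9534414, signal 377). Both were missing from replicate 2.

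The gene for the tagged protein carried one of the strongest peaks. zf30C (FBgn0270924) spans 9758342 to 9762375 on the plus strand of arm 2L. A region from 9757829 to 9759261 had its summit 29 bp downstream of the start of zf30C, a signal of 8287 and rank 3 in all replicates. The same region held a second, intronic summit 751 bp downstream of the start with a signal of 291. The third peak, at 9763179 to 9763618, lay past the end of the gene, 30 bp downstream of a start of und and 137 bp upstream of one of Taf11. Its signal was 325 and its mean percentile 37.3 ± 28.7 (SD, n = 3), with rank 6671 in replicate 3. The flies were transgenic for tagged zf30C, and the number of copies of this locus in them is not given in the sources used here.

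**Figure D2:**
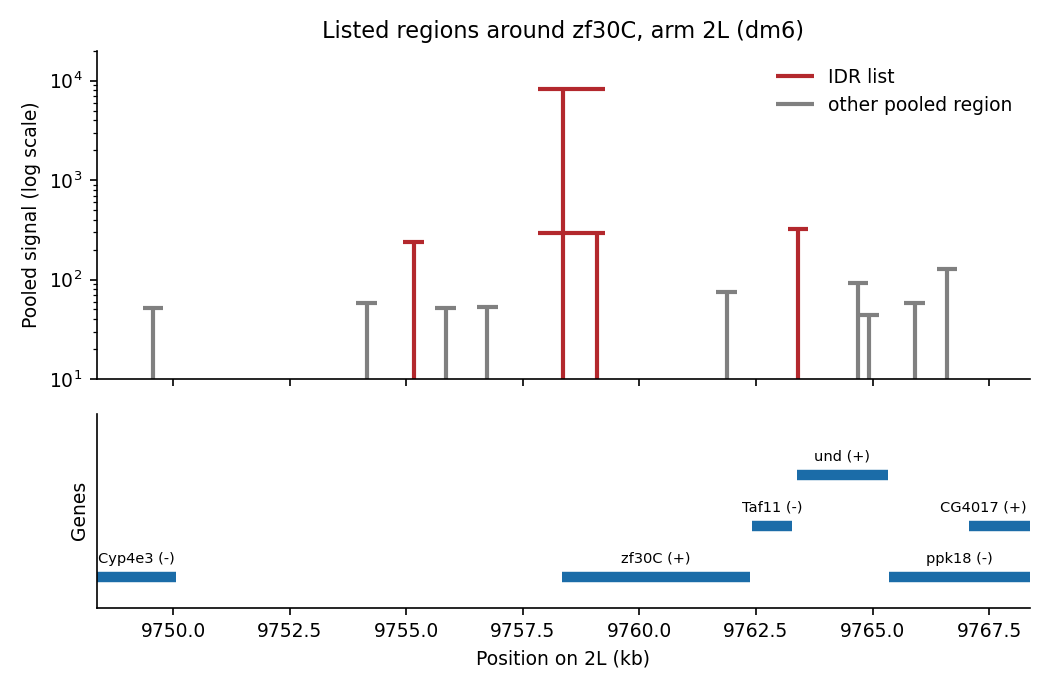
Pooled-list regions within 10 kb of the zf30C promoter summit on arm 2L (dm6): horizontal bars span the regions, vertical bars mark summits at their pooled signal on a log axis, red for the IDR list and grey for other regions, with annotated genes and strands below. The promoter summit reaches 8287 and the next highest summit 325.

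Peaks lay mostly at promoters, in introns and between genes, and almost never in coding exons. Their shares differed from those of all other pooled regions as a whole, but not past the threshold from those of the regions just below the list. Promoters held 1409 peaks, 39.5% (37.9 to 41.1%), against 25.6% of all other regions (odds ratio 1.90, two-sided Fisher's exact test, adjusted p = 4.6e-64). Of the 3567 other regions next in rank 41.1% had a promoter summit, no fewer than in the list (odds ratio 0.94, adjusted exact p = 0.41). Coding exons held 10 peaks, 0.28%, against 6.62% of all other regions (odds ratio 0.040, adjusted exact p = 6.8e-82) and 0.59% of those next in rank (adjusted p = 0.32). Shares were also lower in 3' UTRs (1.32% against 2.69%, adjusted exact p = 4.2e-07) and introns (36.5% against 40.6%, adjusted p = 5.3e-06), while the regions next in rank had 1.37% and 36.3% (adjusted p = 0.92 for both). Intergenic regions held 714 peaks (18.7 to 21.4%), below the 22.3% of all other regions (adjusted exact p = 0.0025) but not below the 18.4% of those next in rank (adjusted p = 0.32). This difference was not past the threshold without replicate 2 (20.8%, adjusted exact p = 0.082), without replicate 3 (21.4%, adjusted p = 0.31), among peaks supported by all replicates (21.2%, adjusted p = 0.27), for the 1783 highest peaks (21.4%, adjusted p = 0.41) or against the higher-ranked part of the other regions (adjusted p = 0.42), and at 24.6% it was no longer below the background with a promoter window of 200 bp. The difference in introns was not past it with that window either (42.4%, adjusted exact p = 0.34). Shares in 5' UTRs (0.95% against 1.10%, adjusted exact p = 0.49) and non-coding exons (1.43% against 1.12%, adjusted p = 0.13) did not pass the threshold. Non-coding exons did pass for the 1783 highest peaks (1.74%, adjusted exact p = 0.040) and with the 200 bp window (2.55%, adjusted p = 0.0042). They also passed against random positions (1.43% against 0.81%, adjusted exact p = 0.00066).

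Promoter summits lay mostly just upstream of the start, at a median position of -53 bp with quartiles at -181 and 29 bp. Upstream positions made up 66.7% of them, against 57.6% at promoters of the other pooled regions.

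**Figure D3:**
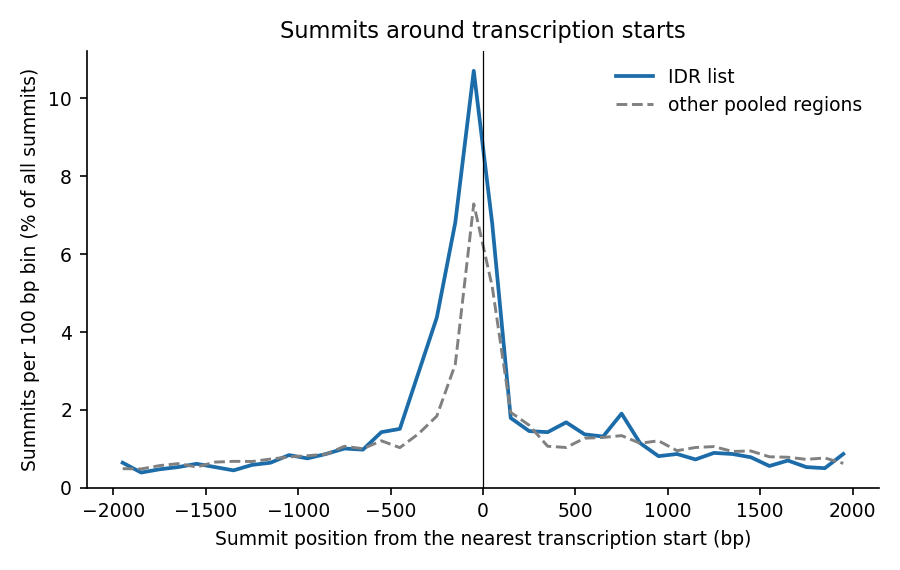
Percent of summits in each 100 bp bin by position from the nearest annotated transcription start (negative is upstream), for the IDR list (blue) and the other pooled regions (grey, dashed). The IDR list reaches 10.7% in the 100 bp upstream of starts, against 7.29%.

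Peaks were spread over the chromosome arms much as the other pooled regions were. Arm 3L held 823 peaks, 3R 807, X 650, 2L 634, 2R 633 and 4 held 20. In Fisher's exact tests 0 of 6 arms passed the threshold after adjustment, and 1 had an unadjusted p under 0.05: arm X, with 18.2% of peaks against 19.7% of other regions (p = 0.038). Against random genomic positions, 2 arms passed: 3L with more peaks (23.1% against 20.9%, adjusted exact p = 0.012) and 4 with fewer (0.56% against 1.05%, adjusted p = 0.012).

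A promoter peak was found at 1346 of the 6151 protein-coding genes that had a pooled region there, 21.9%. Bound genes belonged to divergent pairs, with a start on the other strand within 1000 bp upstream, in 614 of 1346 cases (45.6%, 42.9 to 48.3%), against 46.7% of the 4805 other genes (exact p = 0.48). The share was lower and past the threshold for the 1783 highest peaks (42.4%, exact p = 0.030) and without replicate 1 (42.4%, p = 0.0073). Against the 1500 other genes whose promoters held only the regions next in rank, 52.7% of them in divergent pairs, it was also lower (odds ratio 0.75, exact p = 0.00017).

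Genes for cytosolic ribosomal proteins were bound more often than other genes. Of 81 with a pooled region at the promoter, 46 had a peak (56.8%, 45.3 to 67.8%), against 21.4% of other genes (odds ratio 4.82, adjusted exact p = 1.6e-10). For the 1783 highest peaks the share was 25.9% (adjusted exact p = 0.0014). Among genes with a peak or one of the next 3567 regions at the promoter it was 46 of 65, 70.8%, against 46.7% (odds ratio 2.76, adjusted exact p = 0.0028). The peaks of the bound genes ranked from 818 to 3456. The strongest, 29 bp downstream of a start of RpL7 (FBgn0005593), had pooled rank 818 and a mean percentile of 73.8 ± 10.3 (SD, n = 3). Those of RpS4, RpL24 and RpL28 followed at ranks 878, 1197 and 1233, with percentiles of 71.4 ± 13.7, 61.9 ± 9.0 and 55.9 ± 17.6. Mitochondrial ribosomal protein genes were not bound more often (8 of 47, 17.0%, adjusted exact p = 0.79), although the peak of mRpL41 ranked 88; mRpS10, mRpS23 and mRpL23 followed. Proteasome subunit genes (4 of 18, 22.2%, adjusted exact p = 1.0), with peaks at Rpn3 (rank 139), Rpn10, Rpn12 and Prosalpha2, and translation factor genes (8 of 26, 30.8%, adjusted p = 0.65), led by eIF4EHP, eIF1, eIF6 and eEF2, did not pass the threshold either. The peak of eIF1 is the one of RpL28.

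Genes for insulator and architectural proteins, which organise chromatin domains, were also bound more often: 8 of 13 (61.5%, 31.6 to 86.1%) against 21.8% of other genes (odds ratio 5.74, adjusted exact p = 0.026). They were led by Dref (rank 1328, percentile 55.0 ± 18.9), Cp190 (1479, 41.7 ± 17.6), Chro (1513, 49.1 ± 5.2) and pita (1527, 56.9 ± 7.2; SD, n = 3). The peak of Dref is also that of RpL13, and insv and Elba2 share a peak. The call was lost without replicate 3 (46.2% against 14.2%, adjusted exact p = 0.066), when each summit was given to its nearest gene only (54.5% against 21.6%, adjusted p = 0.13) and among genes with a peak or one of the next 3567 regions (8 of 11 against 47.2%, adjusted p = 1.0). Over all alternatives the adjusted exact p ran from 0.0015 to 1.0.

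tRNA genes were bound less often, 13 of 120 (10.8%, 5.90 to 17.8%) against 21.5% of other genes of all kinds (odds ratio 0.44, adjusted exact p = 0.026). The call was lost without replicate 1 (8.33% against 14.99%, adjusted exact p = 0.22), without replicate 2 (9.17% against 15.3%, adjusted p = 0.33) and without replicate 3 (8.33% against 14.2%, adjusted p = 0.48), in sets with fewer peaks. It was also lost among peaks supported by all replicates (8.33% against 13.0%, adjusted exact p = 0.56) and for the 1783 highest peaks (6.67% against 10.5%, adjusted p = 0.74). Among genes with a peak or one of the next 3567 regions the direction turned, with 13 of 20 bound against 48.0% (adjusted exact p = 1.0). The highest tRNA peaks lay near tRNA:Gln-TTG-2-1 (rank 112), near tRNA:Ser-CGA-1-4 and tRNA:Val-AAC-2-1, which share a peak, and near tRNA:Arg-ACG-1-10. The last of these peaks lies 16 bp from a start of tRNA:Arg-ACG-1-8 and is shared by 4 of the 13 bound tRNA genes, tRNA:Arg-ACG-1-7, tRNA:Arg-ACG-1-8, tRNA:Arg-ACG-1-9 and tRNA:Arg-ACG-1-10. Of the snRNA and snoRNA genes 18 of 76 were bound (23.7%, adjusted exact p = 0.88), with the highest peaks near snoRNA:Me18S-U1356a, snoRNA:hts-a, snoRNA:Psi28S-2949 and snoRNA:Or-aca5. The peak of snoRNA:hts-a is the one of tRNA:Ser-CGA-1-4, and snoRNA:Psi28S-2949 and snoRNA:Or-aca5 share a peak.

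The lists of developmental regulators did not pass the threshold, although single members carried strong peaks. Of genes for segment polarity and signalling 9 of 21 were bound (42.9%, 21.8 to 66.0%, adjusted exact p = 0.15), led by fz3, pnt, ci and aop; with a promoter window of 1000 bp the list passed (11 of 22, adjusted p = 0.045), as it did against all protein-coding genes (adjusted p = 0.00063). Polycomb and Trithorax group genes were bound in 7 of 18 cases (38.9%, adjusted exact p = 0.34), led by Utx (rank 391), ph-p, Su(z)2 and brm. Gap and maternal patterning genes were bound in 5 of 13 cases (38.5%, adjusted exact p = 0.57; Kr, bcd, knrl and ems), pair-rule genes in 4 of 10 (40.0%, adjusted p = 0.61; slp2, Ten-m, hry and slp1) and Hox complex genes in 4 of 12 (33.3%, adjusted p = 0.65; lab at rank 315, Dfd, bcd and Scr). Against all protein-coding genes, whether or not they had a pooled region, the Polycomb and Trithorax, gap, pair-rule and Hox lists passed too, with adjusted p from 0.012 to 0.048.

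Neural genes were bound in 4 of 21 cases (19.0%, adjusted exact p = 1.0): N, which encodes the receptor Notch (rank 259, percentile 91.2 ± 6.0; SD, n = 3), nerfin-1, elav and brat. Of the Enhancer of split complex 3 of 11 were bound (27.3%, adjusted exact p = 0.97), with E(spl)mdelta-HLH at rank 109 (percentile 98.8 ± 0.18; SD, n = 3) and E(spl)mbeta-HLH and E(spl)m2-BFM near the end of the list. Dorsoventral patterning genes were bound in 3 of 15 cases (adjusted exact p = 1.0; Dr, ush and pnr), mesoderm and muscle genes in 2 of 12 (16.7%, adjusted p = 1.0; Act57B and Mef2) and early zygotic genes in 2 of 4 (adjusted p = 0.60; zld and Sxl).

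Genes of DNA replication and the cell cycle were bound in 7 of 25 cases (28.0%, adjusted exact p = 0.79), led by fzr (rank 359), Orc2, dup and twe. Heat shock genes were bound in 4 of 12 cases (33.3%, adjusted exact p = 0.65): Hsp26 (rank 363), Hsp83 (rank 565), Hsc70-3 and Hsp68. Of 6 histone genes with a pooled region 2 were bound (33.3%, adjusted exact p = 0.89), the single-copy variant genes His3.3B (rank 340) and His2Av. Peaks were listed at 0 of 17 chemosensory receptor genes (upper bound 19.5%, adjusted exact p = 0.15), 0 of 3 immune effector genes and 0 of 3 cuticle protein genes (upper bound 70.8% for each, adjusted p = 1.0). With a promoter window of 1000 bp the chemosensory list passed, with 1 of 30 bound (adjusted exact p = 0.043). Against all protein-coding genes chemosensory (0 of 179, adjusted exact p = 2.8e-07) and cuticle protein genes (0 of 117, adjusted p = 8.6e-05) passed. The histone genes turned lower there (2 of 118, adjusted exact p = 0.0034). Many histone genes are multicopy and share reads between copies, so this lower share cannot be read as less binding.

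**Figure D4:**
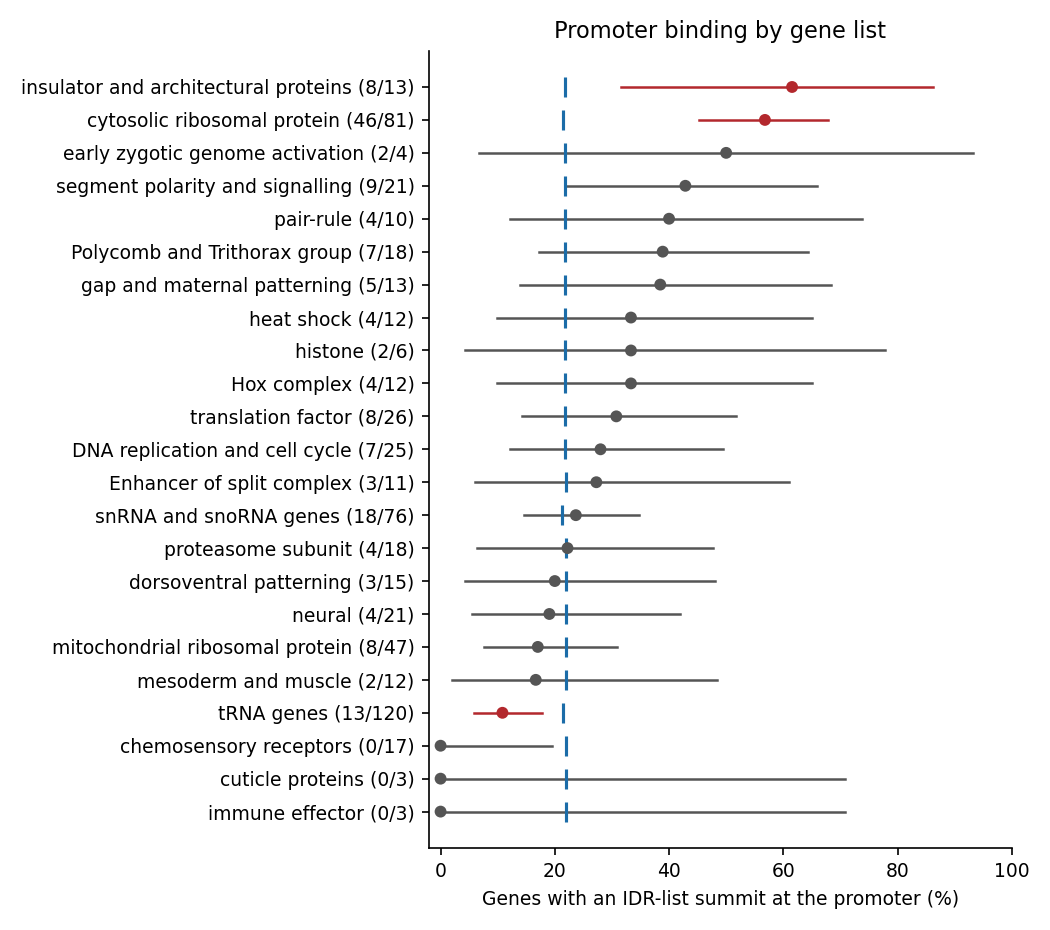
Percent of the genes of each list with an IDR-list summit at the promoter, among genes with a pooled region there (numbers in brackets); points are shares, lines exact 95% intervals, red marks adjusted p under 0.05, and blue ticks the share among other genes. The red lists are insulator and architectural proteins at 61.5%, cytosolic ribosomal proteins at 56.8% and tRNA genes at 10.8%.

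Among 11 known motifs, only that of GAGA factor differed past the threshold from matched pooled regions. GAGAGAG was present in 273 of 3567 summit windows (7.65%, 6.80 to 8.58%), against 4.26% of background windows (odds ratio 1.86, two-sided Fisher's exact test, adjusted p = 1.7e-08). In the narrower window the shares were 2.92% and 2.19%, and the call was lost (adjusted exact p = 0.22). It was also lost against the 3567 other regions next in rank, matched in the same way (8.39% against 7.18%, odds ratio 1.19, adjusted exact p = 0.16). The core CTCF motif was found in 2.35% against 1.49% (adjusted exact p = 0.052), and passed in the narrower window (1.18% against 0.48%, adjusted p = 0.016) and without replicate 2 (2.51%, odds ratio 2.13, adjusted p = 0.0033). It did not pass without replicate 1 (odds ratio 1.71, adjusted exact p = 0.074), without replicate 3 (odds ratio 1.36, adjusted p = 0.28), with 1 summit per region (odds ratio 1.27, adjusted p = 0.39) or against the regions next in rank (odds ratio 1.25, adjusted p = 0.31). The DRE (1.88% against 2.66%) and the BEAF-32 pair (4.04% against 5.19%) both had an adjusted p of 0.087. Both were lower past the threshold for the 1783 highest peaks, with odds ratios of 0.49 and 0.53, and without replicate 3, with 0.58 and 0.69. The BEAF-32 pair also passed without replicate 2 (odds ratio 0.71), among peaks supported by all replicates (0.66) and with 1 summit per region (0.71). It passed too against the regions next in rank (4.41% against 6.75%, odds ratio 0.64, adjusted exact p = 0.00095). It did not pass without replicate 1 (odds ratio 0.76) or in the narrower window (0.85). Against flanks of the same peaks the DRE and the BEAF-32 pair both turned higher, with odds ratios of 2.61 and 1.83. There Motif 1 (5.94% against 2.44%, odds ratio 2.53, adjusted exact p = 6.3e-18), the TATA box (odds ratio 1.51) and the Su(Hw) core (odds ratio 1.24) were also higher past the threshold. Unlike the 6-mer test, these flank tests did not pair each summit window with the flanks of its own peak. Against the main background Motif 1, the Zelda motif, both E-boxes, the TATA box, the Su(Hw) core and the forkhead motif had odds ratios from 0.82 to 1.08 and adjusted p from 0.15 to 0.91.

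The 6-mer with the lowest p at summits was ACACTG. It lay within 50 bp of 707 of 3567 summits (19.8%), against 191 flanks (5.35%), a ratio of 3.70 (exact McNemar test, adjusted p = 6.7e-74). Against flanks 400 bp away the ratio was 5.99, and for the 1783 highest peaks ACACTG ranked 2 by p, with a ratio of 4.51. In the full list it was followed by AGTGTA (18.5% against 5.52%), CACTGA (17.8% against 5.72%), CAGTGC (15.8% against 6.17%), GAGAAA (20.6% against 10.3%) and ACTGAG (11.2% against 4.09%). ACACTG was about as frequent at summits in promoters (275 of 1409, 19.5%), introns (251 of 1302, 19.3%) and intergenic regions (134 of 714, 18.8%), and was found at 20 of 47 summits in 3' UTRs and 14 of 34 in 5' UTRs. In all, 313 of 2080 6-mers were more frequent at summits and 541 in flanks. Summit windows were 37.9% GC and flanks 43.1%. Of the 313 summit words 268 held 2 or fewer G or C, and of the 541 flank words 400 held 4 or more.

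**Figure D5:**
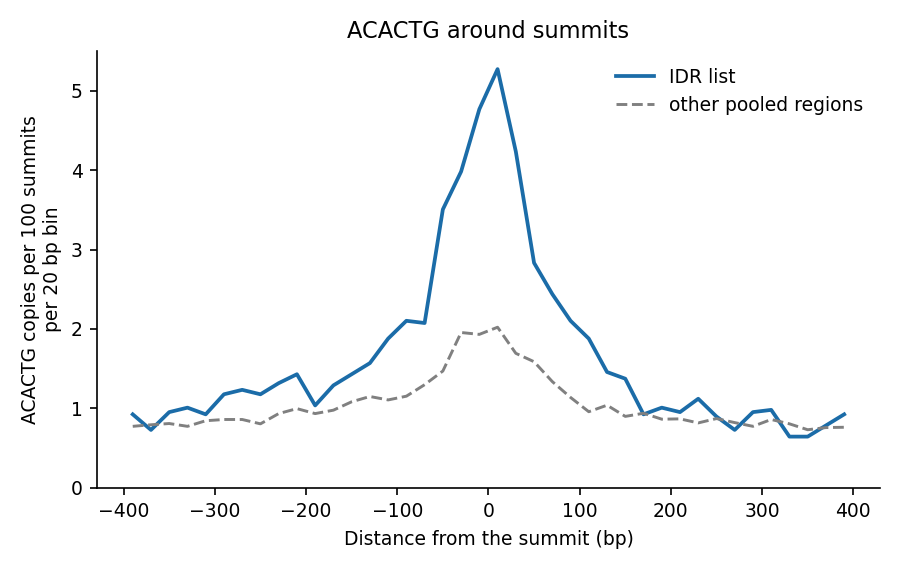
Copies of ACACTG on either strand per 100 summits in each 20 bp bin around the summit, for the IDR list (blue) and the other pooled regions (grey, dashed). The IDR list reaches 5.27 copies per 100 summits in the 20 bp after the summit, against 2.02.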

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

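The alternatives with 1 summit per region, with nearest genes only and with the 3567 other pooled regions next in rank as background were chosen after seeing the data. The promoter share stayed above the background in 10 of 11 alternatives. The exception was the regions next in rank, against which the list's shares at promoters (39.5%), in introns (36.5%) and in intergenic regions (20.02%) lay on the other side of the background and not past the threshold; the weaker pooled regions, with fewer promoter summits, are left out there. Against the regions next in rank the share of divergent pairs, 45.6%, was lower past the threshold, 1 gene list passed, and tRNA genes turned to 65% bound. The ribosomal protein list stayed past the threshold in all of its alternatives, and 6 of 6 arm shares stayed short of it against the regions next in rank. The count of 6-mers more frequent at summits stayed between 241 and 320. For the values below that moved, the cause was not tested unless stated. Support by all 3 replicates was 96.9% for the 1783 highest peaks, 56.3% with summits within 100 bp, 39.3% and 91.3% with N x 0.5 and N x 2 regions, and 71.5 to 74.3% when only 2 replicates were required, which is a looser rule. Mean rank agreement was 0.79; it was 0.86 for the 1783 highest peaks, 0.87 as a Pearson correlation of log2 signal, and 0.74 to 0.83 with a replicate left out. Against random positions 2 arms passed, 3L with an odds ratio of 1.14 and 4 with 0.53, each on the other side of 1 than against pooled regions. With a 200 bp promoter window the intergenic share was 24.6%, no longer below the background, since summits left the promoter class. Genes in divergent pairs made up 42.4% of genes bound by the 1783 highest peaks, and 42.4 to 45.0% with a replicate left out. The count of gene lists was 3; it was 5 with a 1000 bp window, 11 against all protein-coding genes, where the share of bound histone genes fell to 1.69%, since 6 of 118 had a pooled region, and 1 to 2 with a replicate left out. The count of motifs was 1; it was 3 for the 1783 highest peaks, 2 among peaks supported by all 3 replicates, 2 with 1 summit per region, 1 to 3 with a replicate left out, and 6 against flanks of the same peaks. Against flanks, which are not matched on class or GC, the DRE and the BEAF-32 pair turned to odds ratios of 2.61 and 1.83. Depth is unknown, so what it limits could not be assessed. No paired comparison of conditions was possible because there is only 1 group.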

Other observations

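The tests below on zf30C, on ACACTG, on Motif 1, on the longer pattern and on regions below the list, and the counts in this paragraph, were chosen after the result was seen. The tests on the word and on the number of starts at ribosomal protein genes were set before, though the word itself was found in these same data. Some genes held many separate peaks. The most were found in ush, a zinc finger regulator of heart and blood development, with 14 distinct regions over 64.3 kb of arm 2L. It was followed by hth, a homeodomain cofactor of Hox proteins (12 over 132 kb), kirre, a myoblast adhesion protein (11 over 394 kb), pnt, an ETS transcription factor (11 over 55.9 kb), shn (11 over 58.3 kb), CG1677 (10 over 125 kb) and ed (10 over 84.4 kb). These are the 7 genes with 10 or more regions, among 1276 protein-coding genes with a peak inside. They were picked by their counts, and no test against gene length or function was run. Transposable elements held 5 peaks, 0.14%, against 0.26% of other pooled regions (Fisher's exact test, p = 0.21). Only 8 pooled regions outside the IDR list were among the top 3567 regions of all 3 replicates.

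ACACTG was the 6-mer with the lowest p in the full list, and the design has no second group against which a biological explanation was tested. Base composition alone is argued against: among the 179 other 6-mers made of the same bases the median ratio of summit to flank share was 0.91 and the upper quartile 1.09, against 3.70 for ACACTG. Motif 1 of core promoters, which contains ACACT and was itself more frequent at summits than in flanks, is argued against as the whole cause, because the word was more frequent at summits than in flanks away from promoters (432 of 2158 and 4.82%, exact McNemar p = 3.0e-52) and at the 3152 peaks with no Motif 1 match (19.0% and 5.01%, p = 9.3e-67). A 15 bp pattern built from 254 copies of the word on chromosome 2, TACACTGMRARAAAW in ambiguity codes, matched 24.9% of the 1832 summit windows without the word on chromosomes 3, 4 and X, and 6.60% of their flanks (exact McNemar p = 2.8e-53), so a candidate explanation is a sequence that zf30C or a partner recognises, which was not tested directly. Sites with the word may continue below the IDR list, since the next 3567 pooled summits had ACACTG within 50 bp in 15.4% of cases, against 4.77% of the last 3567 (Fisher's exact p = 5.0e-52). Some of these next summits, at ranks 3568 to 7134, lay in regions that overlap the IDR list, which the main background left out.

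The high share of bound ribosomal protein genes stays open to a technical reading. Their number of start sites is argued against, since 1000 draws of other genes matched on it were bound in at most 37.0% of cases, against 56.8%. For signal at highly active promoters without the summit sequence, ACACTG was in 23.9% of the 46 ribosomal protein summits (12.6 to 38.8%), against 19.4% of other promoter peaks (Fisher's exact p = 0.45) and 9.87% of promoter regions outside the list, which met the bound set in advance for ruling that explanation out. That bound is not taken here as ruling it out. The longer pattern was in only 13.0% of the same summits (4.94 to 26.3%). It was in 28.8% of other promoter peaks (Fisher's exact p = 0.019) and 8.11% of promoter regions outside the list. The shares of peaks with the pattern are not held out, since they include promoter peaks on chromosome 2, where the pattern was built. The explanation therefore stays open: signal without the sequence may account for many of these peaks, and no measure of promoter activity was used here to decide it.

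The height of the peak at the promoter of zf30C could come in part from extra copies of the gene brought in with the tag. How large that part is cannot be told apart from binding of zf30C at its own gene. Copies would raise all of the inserted fragment by the same factor. Inside the gene, the other listed summits, at 9759093 and 9761872, had signals of 291 and 74.8. The promoter summit had 8287, and the pooled median was 71.1. The promoter summit thus stood far above the other listed summits of the gene. This cannot decide whether copies are the whole cause of the peak. The unit of the signal is not given, nor whether the fragment held those stretches of the gene. The promoter peak was 25.5 times the strongest other region within 10 kb, at percentile 98.8 among the other promoter peaks with such a ratio. That ratio rises with the peak's own signal and was not compared among peaks of like strength, so it cannot decide. That other region lies at und, past the end of zf30C, and would be raised by copies only if the inserted fragment reached it. There were 9 pooled summits outside the IDR list within 10 kb, at percentile 58.9, which decides nothing for the same reason. The extent of the inserted fragment and its copy number are not given in the sources used here.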
